A study of Arabidopsis thaliana with 48 samples.

How the data were processed

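RNA from the aerial parts of Arabidopsis thaliana Col-0 plants was sequenced from 12 groups of 4 libraries, 48 libraries in all. Plants were 3 weeks old when 20 adult female spider mites (Tetranychus urticae, a sap-feeding arthropod) were placed on each plant of the infested groups. Control plants were grown in parallel without mites, and every plant stood inside a cylinder. Control and infested plants were harvested after 30 min and 24 h, and then after 4, 7, 12 and 15 days. Each library came from a pool of 4 plants, and the labels call the 4 pools of a group biological replicates. Total RNA was used with the NEBNext Ultra kit and read as pairs of 150 bases, per the labels' protocols.

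The values analysed were whole-number read counts per gene and library, as deposited by the authors in a table of 33211 features. The submitters' processing notes name fastp, HISAT2, featureCounts and DESeq2 and the TAIR10 build. Their versions, roles and settings, the annotation release and the use of strand are not given in the sources used here. No strand setting being known, reads of overlapping genes on opposite strands cannot be told apart. Counts of near-identical genes are also uncertain, because reads that map to more than 1 copy can be lost or split. This applies to the defensins PDF1.2, PDF1.2b, PDF1.2c and PDF1.3, to CAB1, CAB2, CAB3 and LHB1B1, to AOC1, AOC2 and AOC3, to SAUR22, SAUR23 and SAUR24, to RBCS1B, RBCS2B and RBCS3B, and to GSTF6 and GSTF7. Gene symbols were taken from the TAIR10.1 annotation by locus name. It matched 32548 of the features, of which 10804 had a symbol other than the locus. The remaining features were 378 without a locus name and 285 genes of the chloroplast and mitochondria. No coordinates are given because the builds differ in name. No column of the table was left out, and no feature was a total or an unassigned class.

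Library totals ranged from 12.5 to 23.4 M counts, with a median of 18.9 M. Before replicates were averaged, their counts were compared over genes. None of the 72 pairs of replicates was identical, and the chi-square per gene lay between 2.63 and 49.8, above sampling noise in every pair. Intervals given for ratios of counts cover counting error only.

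Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group as the criterion, which left 22252 genes, and libraries were scaled by the trimmed mean of M values. Levels are given as scaled counts per M (CPM), mean ± SD over the 4 libraries of a group. A model with 1 coefficient for each of the 12 groups was fitted to all 48 libraries with robust quasi-likelihood dispersion. Infested and control plants were compared at each time with the two-sided quasi-likelihood F-test. Adjusted p-values are Benjamini-Hochberg values within a comparison, and the threshold was 0.05. Genes past the threshold and changed at least 2-fold were counted as a further value. The change of the infestation effect was tested between neighbouring times and over all times as interaction contrasts. Control plants at 15 d were compared with control plants at 30 min, as the labels place the harvests at successive developmental stages. The tests were tried on simulated counts of the 24 h comparison, in which 200 of 22252 genes were changed. The share of changed genes recovered was 66% at 1.5-fold, 92% at 2-fold, 100% at 4-fold and 98% at 8-fold, and 8 of the 186 calls fell on unchanged genes.

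The comparisons, the tests, the rule for named genes and the gene lists were fixed before the data were examined. The 29 lists hold 459 loci, none of them in more than 1 list. They cover jasmonic acid (JA) biosynthesis, JA repressors and turnover, JA-responsive defence proteins, salicylic acid (SA) synthesis and signalling, indole glucosinolates, aliphatic glucosinolates, glucosinolate breakdown, camalexin, flavonoids and anthocyanins, the rapid wound and pattern response, abscisic acid (ABA), ethylene, auxin, cytokinin, and gibberellin and brassinosteroid metabolism. Further lists hold genes of light harvesting, carbon fixation, chlorophyll synthesis, cell division, cell wall loosening, senescence, detoxification, heat shock, flowering time and the circadian clock. Floral organ, seed and root markers and reference genes served as lists of other organs and of genes used for scaling in other assays. Each list was tested at each time with camera (limma 3.58.1, preset correlation 0.01), adjusted over the 174 tests. The same test with an estimated correlation and the rotation test fry were alternatives. Camera compares a list with all other genes, while fry asks whether its genes move one way on balance. Of the 75 camera calls, 7 held with an estimated correlation. Counts of members are given over all genes tested and adjusted over the list alone. In addition, 300 genes most raised and 300 most lowered with age in control plants were tested at the 4 times whose libraries had not given the lists.

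Named genes were the 8 largest rises and 6 largest falls at each time among genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the 4 infested and 4 control libraries. Added to these were up to 4 members of each called list at the time of its lowest p, the 3 largest interactions between neighbouring times, and 16 fixed markers. For a gene with no counts in 1 group, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio of scaled counts is given with an exact 95% interval.

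Alternatives were the RLE normalization, library totals as the only scaling, a block for replicate number within each time, no filter on low counts, fits of only the 8 libraries of a time, DESeq2 1.42.0, and, for infested against control plants at each time, leaving out each library in turn. DESeq2 used the Wald test, and the likelihood ratio test for all times together. After the data were seen, 4 alternatives were added: 30 min libraries thinned to equal totals, organellar features left out, 15 d without the control libraries whose organellar share was above 1%, and age lists of 100 genes. Other groupings of the same libraries were fitted as a test of chance, namely all 35 splits of 8 libraries and 40 or 22 random regroupings for interactions. Random draws that kept the real groups of a time were replaced by other draws. Single scores per library were compared by exact permutation, two-sided, for which 4 against 4 libraries allow no p below 0.029.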

Results

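Gene expression in the rosettes and other aerial parts of Arabidopsis was followed from 30 min to 15 d after spider mites were placed on the plants, with uninfested plants harvested at the same times. Each of the 12 groups had 4 libraries, each from a pool of 4 plants. Mean library totals were 19.3 ± 1.57 M counts (SD, n = 4) for control and 13.7 ± 1.04 M for infested plants at 30 min, the widest gap between the groups of one time. At the other times the group means lay between 17.2 and 20.4 M. The first principal component of log2 CPM took 51% of the variance and the next 12.7%. At every time at least 3059 genes differed between infested and control plants by edgeR's quasi-likelihood test on all 48 libraries. Fits of each time alone gave more up to 4 d and fewer later. Rises of at least 2-fold outnumbered such falls up to 4 d, and the reverse held later.

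**Figure D1:**
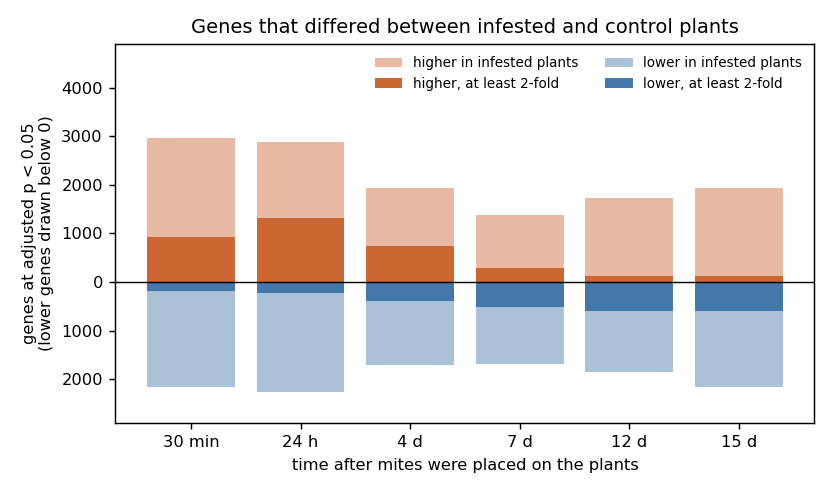
Number of genes that differed between infested and control plants at each time (adjusted p under 0.05), with genes higher in infested plants drawn above 0 and lower genes below 0. Dark parts are genes changed at least 2-fold, of which 1309 were higher at 24 h and 605 were lower at 15 d.

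The comparison at 30 min asks what the plant's RNA shows right after the mites arrive. Among genes with a mean log2 CPM of at least 1, the largest fitted rise was that of CYP82G1 (AT3G25180), a cytochrome P450 that makes the volatile homoterpenes released by attacked leaves, from 0.431 ± 0.66 to 17.2 ± 3.03 CPM (SD, n = 4 per group; log2 fold change 5.19, SE 0.56, adjusted p = 2.3e-09). The calmodulin-like calcium sensor CML37 (AT5G42380) rose by a log2 fold change of 4.71 (adjusted p = 1.1e-08), and the transcription factor genes MYB15 (AT3G23250), ZAT7 (AT3G46090) and ERF13 (AT2G44840) by 4.69, 4.55 and 4.36. BAP1 (AT3G61190), a negative regulator of cell death, rose by 4.15. WRKY62 (AT5G01900) had 28 counts in infested and 1 in control plants, a ratio of 40.7 (95% interval 6.73 to 1660). ELI3-2 (AT4G37990), an alcohol dehydrogenase gene, rose by 4.52 (adjusted p = 0.021), but its call ended without control replicate 2, control replicate 4 or infested replicate 1 (adjusted p = 0.058, 0.056 and 0.073; range over all alternatives 6.5e-05 to 0.082). Among the falls were the phosphatase gene PAP16 (AT3G10150) at -2.22, the sucrose exporter gene SWEET13 (AT5G50800) at -1.94, the cell wall enzyme gene XTH15 (AT4G14130) at -1.81 and CYP707A2 (AT2G29090), an enzyme of ABA breakdown, at -1.8. SAG29 (AT5G13170), a senescence-linked sugar transporter gene, and the galactinol synthase gene GolS2 (AT1G56600) were at -5.26 and -1.85. Without control replicate 1 their adjusted p was 0.62 and 0.4 (ranges over the alternatives 1.1e-06 to 0.62 and 0.00011 to 0.4), and the SAG29 call also ended without any of the infested replicates (highest adjusted p = 0.1). In all, 2956 genes were higher and 2160 lower in infested plants, of which 934 and 189 changed at least 2-fold. With library totals as the only scaling the split was 2506 higher and 2735 lower.

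The rapid wound and ethylene lists and 2 of the 3 JA lists were called higher at 30 min. JA-responsive defence proteins were not (6 of 21 higher and 0 lower, adjusted p = 0.2). Of the 29 measured genes of the rapid wound and pattern response, 22 rose and 1 fell (22 and 1 adjusted over the list alone; camera adjusted p = 2.3e-17, and adjusted p = 0.06 with an estimated correlation). The transcription factors RHL41 (AT5G59820, also ZAT12) and WRKY40 (AT1G80840) went from 1.14 ± 1.03 to 16.6 ± 2.29 CPM and from 6.84 ± 3.31 to 93.6 ± 8.46 CPM (log2 fold changes 3.82 and 3.75). Ethylene synthesis and perception was the one list of this time whose call held with an estimated correlation, with 9 of 13 genes higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 6.8e-07, and 0.0038 with an estimated correlation). Its ACS7 (AT4G26200), a rate-limiting ACC synthase, had 67 counts in infested and 0 in control plants, at least 32.4-fold higher. The other synthesis genes ACO1 (AT2G19590), ACS8 (AT4G37770) and EFE (AT1G05010) rose by log2 fold changes of 1.66, 1.11 and 0.82. JA biosynthesis had 10 of 13 genes higher and 0 lower (10 and 0 adjusted over the list alone; adjusted p = 1.2e-07, and adjusted p = 0.17 with an estimated correlation). JA repressors and turnover had 15 of 21 higher and 0 lower (19 and 0 over the list alone; adjusted p = 5.2e-08, and adjusted p = 0.31 with an estimated correlation). The JA synthesis gene AOS (AT5G42650) tripled from 256 ± 124 to 774 ± 115 CPM (log2 fold change 1.59, adjusted p = 2.7e-05). JAZ10 (AT5G13220), a JA repressor, rose by 1.56 (adjusted p = 0.033), a call that ended without control replicate 1, 3 or 4 or infested replicate 1 (adjusted p = 0.056, 0.083, 0.12 and 0.11; range over the alternatives 0.0091 to 0.16).

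The SA, indole glucosinolate and camalexin lists, which hold genes of defence against microbes and feeding animals, were also called higher at 30 min. Aliphatic glucosinolates (0 higher and 1 lower of 24, adjusted p = 0.18) and glucosinolate breakdown (1 and 1 of 9, adjusted p = 0.43) were not called. SA synthesis and signalling had 11 of 27 genes higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 4.5e-05, and adjusted p = 0.38 with an estimated correlation). Indole glucosinolate genes were higher in 10 of 19 cases and lower in 0 (11 and 1 over the list alone; adjusted p = 1.7e-06, and adjusted p = 0.16 with an estimated correlation). Camalexin genes rose in 4 of 6 cases (4 over the list alone; adjusted p = 2e-04, and adjusted p = 0.13 with an estimated correlation). Auxin response genes were lower in 10 of 16 cases and higher in 1 (11 and 2 over the list alone; adjusted p = 0.00061, and adjusted p = 0.38 with an estimated correlation). Cell wall loosening had 6 of 13 genes lower and 1 higher (7 and 2 over the list alone; adjusted p = 0.024, and adjusted p = 0.31 with an estimated correlation). Chlorophyll synthesis had 3 of 13 genes lower and 0 higher (3 and 0 over the list alone; adjusted p = 0.021, and adjusted p = 0.51 with an estimated correlation). Cell division had 1 of 21 genes lower and 0 higher (0 and 0 over the list alone; adjusted p = 0.046, and adjusted p = 0.71 with an estimated correlation), a call that also ended with fry (0.14) and with replicate number as a block (0.059). Flowering time and meristem identity had 4 of 13 genes lower and 0 higher (4 and 0 over the list alone; adjusted p = 0.027, and adjusted p = 0.24 with an estimated correlation). These 4 were SPL9 (AT2G42200), SPL5 (AT3G15270) and SPL4 (AT1G53160), which promote the change to the adult phase and flowering, at -0.84, -0.81 and -0.58, and the meristem identity gene AGL8 (AT5G60910) at -0.50. The AGL8 call ended when 6 of the 8 libraries were left out singly, all but control replicate 4 and infested replicate 4 (highest adjusted p = 0.1; lowest over the alternatives 0.011).

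**Figure D2:**
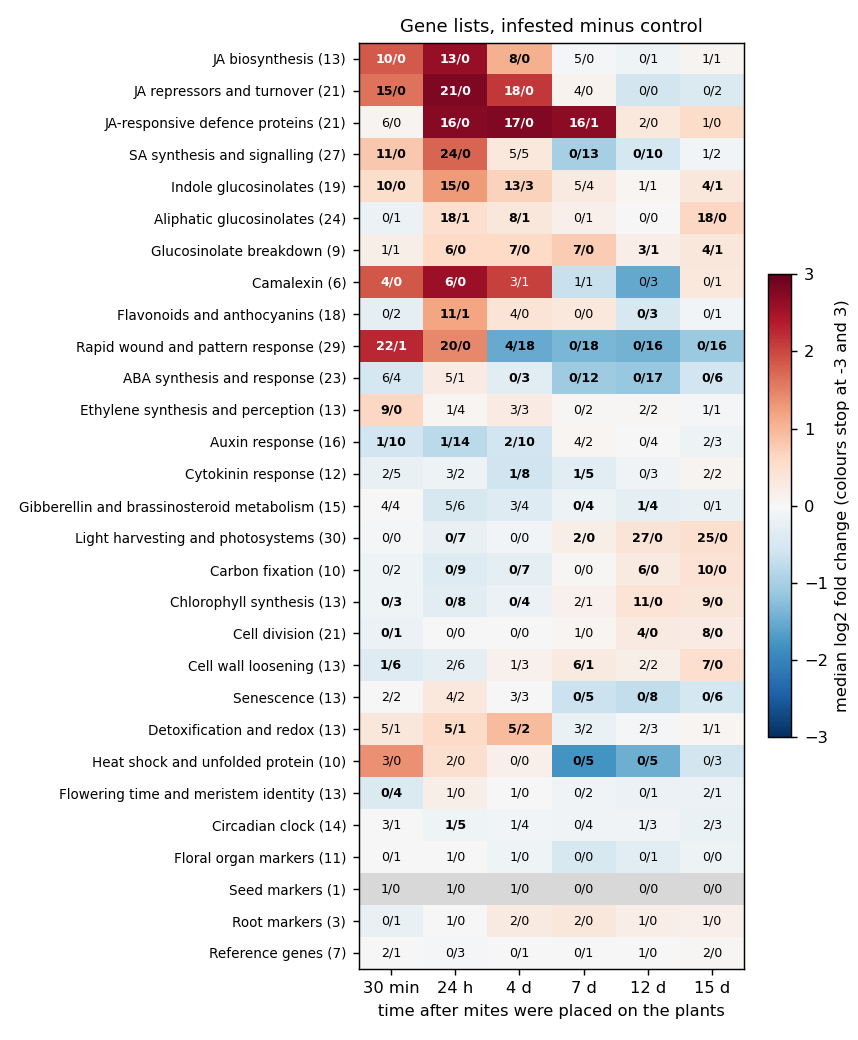
Median fitted log2 fold change (infested minus control, colour) of the measured genes of each list fixed in advance, with the number of measured genes beside the list name and the times on the horizontal axis. Numbers in the cells are genes higher and lower at adjusted p under 0.05, bold where the camera test of the list passed, and the single measured seed marker is drawn in grey; JA repressors and turnover reached 21 higher and 0 lower at 24 h, and light harvesting 27 and 0 at 12 d.

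At 24 h the 3 JA lists and the SA list were called higher (adjusted p between 0.06 and 0.077 with an estimated correlation). MDHAR (AT3G09940), a monodehydroascorbate reductase, rose from 1.59 ± 2.47 to 113 ± 31 CPM (log2 fold change 6.11, SE 0.60, adjusted p = 6.6e-10). MSRB7 (AT4G21830), which repairs oxidised methionine, rose by 6.22 (SE 0.73, adjusted p = 3.6e-08), WRKY62 by 5.94 and ELI3-2 by 5.31. PAD3 (AT3G26830), the enzyme of the last step of camalexin synthesis, rose by 5.98 (SE 1.1, adjusted p = 6e-05). DXPS1 (AT3G21500), an isoprenoid pathway gene, had 87 counts in infested and 1 in control plants, a ratio of 97.5 (95% interval 17 to 3890). For the glucosyltransferase gene UGT76B1 (AT3G11340) the ratio was 54.5 (18.3 to 268). CSLG2 (AT4G24000), a cellulose synthase-like gene, had 40 counts against 0, at least 14.9-fold higher. Its call ended without infested replicate 2 (adjusted p = 0.078; range over the alternatives 1.5e-05 to 0.078). Among the falls, the auxin response gene IAA29 (AT4G32280) went from 15.9 ± 3.28 to 2.18 ± 0.483 CPM (log2 fold change -2.86, SE 0.29, adjusted p = 4.6e-10). WOX2 (AT5G59340), a homeobox gene, fell by 2.80, the brassinosteroid synthesis gene BR6OX1 (AT5G38970) by 2.43, the wax alcohol gene CER4 (AT4G33790) by 2.11, the brassinosteroid-responsive BEE3 (AT1G73830) by 2.09 and the wall enzyme gene XTH17 (AT1G65310) by 2.08. Altogether 2882 genes were higher and 2275 lower, 1309 and 224 of them at least 2-fold, and library totals as the only scaling gave 2647 and 2762.

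Every measured JA synthesis gene rose at 24 h, 13 of 13 (13 adjusted over the list alone; camera adjusted p = 3.3e-15, and adjusted p = 0.06 with an estimated correlation). AOC3 (AT3G25780) went from 4.76 ± 3.92 to 56.1 ± 11.6 CPM and AOC1 (AT3G25760), with LOX4 (AT1G72520) and LOX3 (AT1G17420), rose by log2 fold changes of 3.35, 3.27 and 2.92. LOX2 (AT3G45140), the main leaf lipoxygenase of the pathway, rose from 1740 ± 1350 to 10600 ± 1970 CPM (log2 fold change 2.61, adjusted p = 8.6e-06). All 21 JA repressors and turnover genes rose too (21 over the list alone; adjusted p = 2.5e-19, and adjusted p = 0.077 with an estimated correlation). CYP94B3 (AT3G48520), AT3G11180 and AT2G38240, which inactivate JA by oxidation, and the sulfotransferase gene ST2A (AT5G07010) rose by 4.39, 3.99, 3.95 and 3.69. JA-responsive defence proteins had 16 of 21 genes higher and 0 lower (16 and 0 over the list alone; adjusted p = 4.4e-11, and adjusted p = 0.077 with an estimated correlation), among them the storage protein VSP2 (AT5G24770) at 2.37 (adjusted p = 0.00028). SA synthesis and signalling had 24 of 27 genes higher and 0 lower (26 and 0 over the list alone; adjusted p = 2.3e-17, and adjusted p = 0.06 with an estimated correlation). ALD1 (AT2G13810), which starts pipecolic acid synthesis, had 121 counts against 2, a ratio of 67.8 (95% interval 18.4 to 566). PR1 (AT2G14610), a marker of the SA response, was at 20.7 ± 23.5 CPM against 0.527 ± 0.284 (log2 fold change 5.28, adjusted p = 0.00084), and its adjusted p was 0.06 in a fit of the 8 libraries of this time alone (lowest over the alternatives 9.9e-08). The SA synthesis gene EDS16 (AT1G74710, also ICS1) was at 0.44 (adjusted p = 0.17).

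Lists of specialised metabolism were also called higher at 24 h. Indole glucosinolate genes were higher in 15 of 19 cases and lower in 0 (15 and 0 adjusted over the list alone; adjusted p = 2.8e-18, and 0.015 with an estimated correlation). The modifying enzymes IGMT5 (AT1G76790) and CYP81F4 (AT4G37410) and the entry enzymes CYP79B3 (AT2G22330) and CYP79B2 (AT4G39950) rose by log2 fold changes of 3.65, 2.83, 2.62 and 2.60. Glucosinolate breakdown had 6 of 9 genes higher and 0 lower (6 and 0 over the list alone; adjusted p = 3.5e-06, and 0.028 with an estimated correlation). Aliphatic glucosinolate genes were higher in 18 of 24 cases and lower in 1 (19 and 1 over the list alone; adjusted p = 4.6e-06, and adjusted p = 0.43 with an estimated correlation). Their regulator MYB28 (AT5G61420) fell by 0.54 on the log2 scale (adjusted p = 1.5e-05) while the entry enzyme CYP79F1 (AT1G16410) rose by 0.68 (adjusted p = 0.0027). All 6 camalexin genes rose (6 over the list alone; adjusted p = 1.7e-05, and adjusted p = 0.077 with an estimated correlation). CYP71A13 (AT2G30770) had 222 counts against 1, a ratio of 249 (95% interval 44.2 to 9870), and GSTF7 (AT1G02920) and CYP71A12 (AT2G30750) rose by 2.59 and 2.52. Flavonoid and anthocyanin genes were higher in 11 of 18 cases and lower in 1 (11 and 1 over the list alone; adjusted p = 0.0017, and adjusted p = 0.51 with an estimated correlation), with the regulator PAP1 (AT1G56650) and the enzymes UF3GT (AT5G54060), DFR (AT5G42800) and AT5MAT (AT3G29590) at 1.70, 1.48, 1.47 and 1.46. Detoxification and redox genes were higher in 5 of 13 cases and lower in 1 (8 and 1 over the list alone; adjusted p = 0.017, and adjusted p = 0.18 with an estimated correlation). The rapid response list had 20 of 29 genes higher and 0 lower (24 and 0 over the list alone; adjusted p = 1.8e-13, and adjusted p = 0.077 with an estimated correlation).

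The auxin response, photosynthesis and chlorophyll lists were called lower at 24 h, while cell division (0 of 21 genes passing, adjusted p = 0.83) and cell wall loosening (2 higher and 6 lower of 13, adjusted p = 0.12) were not called. Auxin response had 14 of 16 genes lower and 1 higher (14 and 1 adjusted over the list alone; adjusted p = 8.2e-09, and adjusted p = 0.12 with an estimated correlation). The growth-linked SAUR22 (AT5G18050), SAUR23 (AT5G18060) and SAUR24 (AT5G18080), whose near-identical copies make the counts of each uncertain, were at -1.42, -1.42 and -1.24. Carbon fixation had 9 of 10 genes lower and 0 higher (10 and 0 over the list alone; adjusted p = 1.2e-06, and adjusted p = 0.23 with an estimated correlation). Light harvesting had 7 of 30 lower and 0 higher (7 and 0 over the list alone; adjusted p = 2e-04, and adjusted p = 0.64 with an estimated correlation). Chlorophyll synthesis had 8 of 13 genes lower and 0 higher (11 and 1 over the list alone; adjusted p = 2e-04, and adjusted p = 0.28 with an estimated correlation). The circadian clock list had 5 of 14 genes lower and 1 higher (5 and 1 over the list alone; adjusted p = 0.013, and adjusted p = 0.23 with an estimated correlation). The morning genes CCA1 (AT2G46830) and LHY (AT1G01060) and the coactivator AT3G54500 fell by 0.82, 0.67 and 0.62 on the log2 scale. PRR5 (AT5G24470), expressed later in the day, rose by 1.24 (adjusted p = 0.014, and 0.057 without control replicate 4; range over the alternatives 0.0074 to 0.057). Infestation was thus not separated from the hour of harvest at 24 h.

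At 4 d the 3 JA lists were called higher and the rapid wound list lower (adjusted p between 0.06 and 0.14 with an estimated correlation). DXPS1 had 379 counts in infested plants against 1, a ratio of 360 (95% interval 64.3 to 14300), and the transcription factor gene NAC025 (AT1G61110) 106 against 1, a ratio of 101 (17.7 to 4020). MDHAR was at 46.4 ± 15.6 CPM against 0.559 ± 0.41 (log2 fold change 6.37, SE 0.69, adjusted p = 1e-08). The defensin gene PDF1.4 (AT1G19610) rose by 5.75 (SE 0.46, adjusted p = 6.1e-12), MSRB7 by 6.70, CYP82G1 by 5.50, the receptor-like protein gene RLP40 (AT3G24982) by 5.44 and the trypsin inhibitor gene TI1 (AT2G43510) by 5.11. The ethylene response factor genes ERF104 (AT5G61600), ERF5 (AT5G47230) and ERF6 (AT4G17490) were lower in infested plants at -4.24, -3.83 and -3.71, with ERF104 at 2.58 ± 0.751 CPM against 48.7 ± 11.6 in control plants (adjusted p = 3.9e-10). The cold-response regulator CBF2 (AT4G25470) was at -4.04 and BT2 (AT3G48360), a scaffold protein gene, at -3.55. FRO1 (AT1G01590), a ferric reductase gene, had 3 counts in infested and 43 in control plants, 15-fold higher in the controls (95% interval 4.83 to 76). In total 1932 genes were higher and 1710 lower, 750 and 384 of them at least 2-fold. Library totals as the only scaling gave 1727 and 1941, and a fit of the 8 libraries of this time alone 2636 and 2746.

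JA-responsive defence proteins had 17 of 21 genes higher and 0 lower at 4 d (20 and 0 adjusted over the list alone; camera adjusted p = 1.6e-15, and adjusted p = 0.06 with an estimated correlation). TI1 went from 2.47 ± 1.5 to 86.1 ± 14.6 CPM. The acetyltransferase gene NATA1 (AT2G39030), the terpene synthase gene TPS04 (AT1G61120) and the thionin gene THI2.1 (AT1G72260) rose by log2 fold changes of 4.76, 4.58 and 4.34, and the defensin PDF1.2 (AT5G44420) by 2.77 (adjusted p = 0.0045, and 0.14 with DESeq2; range over the alternatives 1.4e-07 to 0.16). JA biosynthesis had 8 of 13 genes higher and 0 lower (8 and 0 over the list alone; adjusted p = 1.3e-08, and adjusted p = 0.14 with an estimated correlation). JA repressors and turnover had 18 of 21 higher and 0 lower (19 and 0 over the list alone; adjusted p = 5.8e-19, and adjusted p = 0.077 with an estimated correlation). Glucosinolate breakdown rose in 7 of 9 genes and fell in 0 (7 and 0 over the list alone; adjusted p = 8.3e-10, and 0.0038 with an estimated correlation). Among them the nitrilase NIT2 (AT3G44300), MVP1 (AT1G54030), the nitrile specifier NSP1 (AT3G16400) and the myrosinase TGG2 (AT5G25980) were at 3.68, 1.5, 1.41 and 0.91. Indole glucosinolate genes were higher in 13 of 19 cases and lower in 3 (13 and 3 over the list alone; adjusted p = 1.9e-07, and adjusted p = 0.11 with an estimated correlation). Aliphatic glucosinolate genes were higher in 8 of 24 and lower in 1 (11 and 1 over the list alone; adjusted p = 0.00049, and adjusted p = 0.55 with an estimated correlation). MYB28 stayed lower at -0.31 (adjusted p = 0.017), which ended without control replicate 3 or infested replicate 2 or 4 (adjusted p = 0.073, 0.05 and 0.063; range over the alternatives 7e-04 to 0.073). Detoxification and redox had 5 of 13 genes higher and 2 lower (7 and 2 over the list alone; adjusted p = 0.00054, and adjusted p = 0.069 with an estimated correlation), with GSTU4 (AT2G29460), GSTU10 (AT1G74590) and the copper superoxide dismutase CSD1 (AT1G08830) at 3.24, 2.1 and 1.21 and the iron form FSD1 (AT4G25100) at -1.13.

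The rapid wound and pattern genes were now lower in infested than in control plants, 18 of 29 lower and 4 higher (19 and 7 adjusted over the list alone; adjusted p = 2.5e-13, and adjusted p = 0.077 with an estimated correlation). Over the 29 genes the mean log2 CPM was 3.79 ± 0.46 in control and 2.57 ± 0.12 in infested plants at 4 d (SD, n = 4), after 1.65 ± 0.28 and 3.38 ± 0.25 at 24 h. Groups did not overlap at either time (exact permutation, two-sided, adjusted p = 0.035 over 6 times). Cytokinin response had 8 of 12 genes lower and 1 higher (8 and 1 over the list alone; adjusted p = 1.1e-07, and 0.033 with an estimated correlation). The response regulators ARR7 (AT1G19050), RR5 (AT3G48100) and ARR15 (AT1G74890) were at -1.26, -1.26 and -1.01 and CKX5 (AT1G75450), which degrades cytokinin, at 0.97. Auxin response had 10 of 16 genes lower and 2 higher (10 and 3 over the list alone; adjusted p = 4.1e-05, and adjusted p = 0.28 with an estimated correlation). Carbon fixation had 7 of 10 lower and 0 higher (7 and 0 over the list alone; adjusted p = 6.7e-05, and adjusted p = 0.34 with an estimated correlation). Chlorophyll synthesis had 4 of 13 lower and 0 higher (7 and 1 over the list alone; adjusted p = 0.0017, and adjusted p = 0.37 with an estimated correlation). ABA synthesis and response had 3 of 23 lower and 0 higher (3 and 0 over the list alone; adjusted p = 0.0074, and adjusted p = 0.61 with an estimated correlation).

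**Figure D3:**
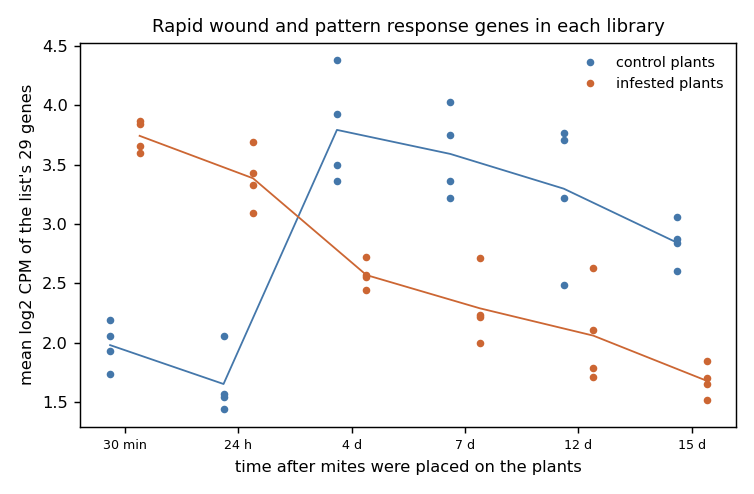
Mean log2 CPM of the 29 measured rapid wound and pattern response genes in each library (points) at each time, with lines joining the means of the 4 control and the 4 infested libraries. Infested libraries lay above the controls at 30 min and 24 h and below them at 4 d, 7 d and 15 d, with overlap at 12 d; the control mean went from 1.65 at 24 h to 3.79 at 4 d.

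At 7 d several plant defensin genes were among the largest rises. PDF1.2 went from 0.348 ± 0.368 to 109 ± 45.7 CPM (log2 fold change 8.31, SE 1.04, adjusted p = 3.8e-07) and PDF1.2c (AT5G44430) rose by 9.09 (adjusted p = 4.2e-07). PDF1.2b (AT2G26020) and PDF1.3 (AT2G26010) had no counts in the control libraries and were at least 397-fold and 394-fold higher. These copies are near-identical, so the share of each is uncertain. AACT1 (AT5G61160), an acyltransferase gene, had 747 counts against 2, a ratio of 425 (95% interval 117 to 3520). PDF1.4 rose by 6.34 (SE 0.53, adjusted p = 1.8e-11), NATA1 by 5.57 (SE 1.14, adjusted p = 0.00062) and BSMT1 (AT3G11480), which makes methyl salicylate and methyl benzoate, by 5.17. Among the falls, the transcription factor gene WRKY53 (AT4G23810) was at 6.46 ± 1.6 CPM against 80.3 ± 20 (log2 fold change -3.64, SE 0.32, adjusted p = 5.4e-10). The ubiquitin ligase PUB19 (AT1G60190), BT2, PP2-B13 (AT1G56240) and DIP2 (AT5G03210) were at -4.36, -4.28, -4.37 and -3.50. RRTF1 (AT4G34410) was at -4.72, but without control replicate 1 its adjusted p was 0.21 (range over the alternatives 6e-05 to 0.21). In all 1371 genes were higher and 1688 lower, of which 286 and 521 changed at least 2-fold. With library totals as the only scaling there were 955 higher and 2138 lower genes, and without control replicate 2 or 3 the higher genes numbered 814 or 818.

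JA-responsive defence proteins were called higher at 7 d, with 16 of 21 higher and 1 lower (16 and 1 adjusted over the list alone; camera adjusted p = 3.1e-12, and adjusted p = 0.077 with an estimated correlation), while JA biosynthesis was not called as a list (median log2 fold change -0.05, mean 0.38, adjusted p = 0.15). LOX2 was at 2.13 (adjusted p = 0.00032) and VSP2 at 2.17 (adjusted p = 0.0016). AOS was at 0.84 (adjusted p = 0.034), a call that ended when control replicate 2, 3 or 4 or infested replicate 1, 2 or 3 was left out (highest adjusted p = 0.12; lowest over the alternatives 0.00059). Glucosinolate breakdown had 7 of 9 genes higher and 0 lower (7 and 0 over the list alone; adjusted p = 4e-09, and 0.0038 with an estimated correlation). ABA synthesis and response had 12 of 23 genes lower and 0 higher (15 and 0 over the list alone; adjusted p = 1.1e-14, and adjusted p = 0.077 with an estimated correlation). RD26 (AT4G27410), an ABA-induced transcription factor, went from 147 ± 41.1 to 18.9 ± 3.57 CPM in infested plants (log2 fold change -2.96, adjusted p = 1.8e-07), with CYP707A3 (AT5G45340) at -2.90 and NCED3 (AT3G14440), the key enzyme of ABA synthesis, at -2.55. The phosphatase gene HAI2 (AT1G07430) was at -2.94 (adjusted p = 0.014, and 0.062 without control replicate 2; range over the alternatives 5e-04 to 0.062). The rapid response list had 18 of 29 genes lower and 0 higher (20 and 1 over the list alone; adjusted p = 8.2e-16, and adjusted p = 0.06 with an estimated correlation). SA synthesis and signalling had 13 of 27 lower and 0 higher (18 and 1 over the list alone; adjusted p = 8.9e-07, and adjusted p = 0.28 with an estimated correlation).

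Further lists were called at 7 d. Senescence had 5 of 13 genes lower and 0 higher (6 and 0 adjusted over the list alone; adjusted p = 1.4e-06, and adjusted p = 0.077 with an estimated correlation). Cytokinin response had 5 of 12 lower and 1 higher (5 and 1 over the list alone; adjusted p = 0.0086, and adjusted p = 0.24 with an estimated correlation). Gibberellin and brassinosteroid metabolism had 4 of 15 lower and 0 higher (4 and 0 over the list alone; adjusted p = 0.014, and adjusted p = 0.06 with an estimated correlation). Its synthesis genes GA3OX1 (AT1G15550) and BR6OX2 (AT3G30180) were at -1.82 and -1.13 and ATGA2OX1 (AT1G78440), which inactivates gibberellin, at -1.51. The BR6OX2 call ended in a fit of these 8 libraries alone (adjusted p = 0.14; lowest over the alternatives 8.7e-06). The receptor gene GID1B (AT3G63010) was at -0.59 (adjusted p = 0.032), a call that ended without control replicate 2 or 3 or infested replicate 3 or 4 (adjusted p = 0.23, 0.085, 0.14 and 0.055; lowest over the alternatives 0.013). Heat shock had 5 of 10 genes lower and 0 higher (6 and 0 over the list alone; adjusted p = 0.02, and adjusted p = 0.37 with an estimated correlation), and the adjusted p was 0.05 with library totals as the only scaling and 0.062 with replicate number as a block. Light harvesting had 2 of 30 genes higher and 0 lower (1 and 0 over the list alone; adjusted p = 2.4e-05, and adjusted p = 0.58 with an estimated correlation). Cell wall loosening had 6 of 13 higher and 1 lower (7 and 1 over the list alone; adjusted p = 0.002, and adjusted p = 0.16 with an estimated correlation).

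At 12 d the senescence list was called lower (8 of 13 genes, adjusted p = 0.06 with an estimated correlation) and light harvesting higher (27 of 30, 0.19). SAG12 (AT5G45890), a cysteine protease of ageing leaves, was at 0.424 ± 0.29 CPM in infested and 24 ± 11 CPM in control plants (log2 fold change -5.82, SE 0.51, adjusted p = 2.4e-07). Both groups had at most a few counts of it at the 4 earlier times, and at 15 d the groups were at 63.4 ± 24.7 and 50 ± 17.9 CPM (adjusted p = 0.5). DIP2 and DXPS1 were at -3.51 and -3.23. SAG29 was at -4.12 (adjusted p = 0.00059, and 0.092 without control replicate 4; range over the alternatives 9.3e-06 to 0.14). DOX1 (AT3G01420), an alpha-dioxygenase, was at -3.11 (adjusted p = 0.031), and its call ended without control replicate 2 or 4 or infested replicate 1, 2 or 3 (highest adjusted p = 0.12; lowest over the alternatives 0.0038). AACT1 had 172 counts in infested and 3 in control plants, a ratio of 64.2 (95% interval 21.6 to 314). EARLI1 (AT4G12480), PDF1.4 and the chitin-binding PR4 (AT3G04720) rose by 3.33, 2.21 and 1.8, and the chlorophyll-binding LHB1B1 (AT2G34430) from 517 ± 87.4 to 1520 ± 383 CPM (log2 fold change 1.56, adjusted p = 5.3e-06). CHX16 (AT1G64170), a cation exchanger gene, and NSP4 (AT3G16410), a nitrile specifier gene, rose by 1.65 and 1.55. LAS1 (AT3G45130), lanosterol synthase, rose by 1.82 (adjusted p = 0.031), which held in none of the fits without a library except the one without infested replicate 2 (highest adjusted p = 0.095 and lowest 0.00058 over the alternatives). FT (AT1G65480), the mobile flowering signal, was at 1.52 ± 0.453 CPM against 7.62 ± 4.96 (log2 fold change -2.33, adjusted p = 5.3e-05). In total 1731 genes were higher and 1847 lower, 122 and 605 at least 2-fold. Library totals as the only scaling gave 1003 higher and 2872 lower genes, a fit of these 8 libraries alone 959 and 1080, no filter 1804 and 1532, a block for replicate number 1955 and 1805, and leaving out control replicate 4 left 1097 higher.

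Light harvesting genes were higher in 27 of 30 cases and lower in 0 at 12 d (29 and 0 adjusted over the list alone; camera adjusted p = 2.8e-18, and adjusted p = 0.19 with an estimated correlation). Chlorophyll synthesis had 11 of 13 genes higher and 0 lower (13 and 0 over the list alone; adjusted p = 8.5e-14, and 0.044 with an estimated correlation), with PORB (AT4G27440), PORA (AT5G54190), CHLM (AT4G25080) and CHLI1 (AT4G18480) at 1.02, 0.98, 0.55 and 0.52. Carbon fixation had 6 of 10 higher and 0 lower (9 and 0 over the list alone; adjusted p = 9.9e-05, and adjusted p = 0.34 with an estimated correlation). Cell division had 4 of 21 higher and 0 lower (8 and 0 over the list alone; adjusted p = 0.00063, and adjusted p = 0.51 with an estimated correlation). Senescence had 8 of 13 genes lower and 0 higher (9 and 0 over the list alone; adjusted p = 9.3e-08, and adjusted p = 0.06 with an estimated correlation). SAG21 (AT4G02380) and SAG13 (AT2G29350) were at -1.62 and -1.85, the call of SAG13 ending without control replicate 2 (adjusted p = 0.053; range over the alternatives 0.0011 to 0.066). ABA synthesis and response had 17 of 23 lower and 0 higher (21 and 0 over the list alone; adjusted p = 2.5e-10, and adjusted p = 0.17 with an estimated correlation). The rapid response had 16 of 29 lower and 0 higher (23 and 0 over the list alone; adjusted p = 1.4e-14, and adjusted p = 0.069 with an estimated correlation). SA synthesis and signalling had 10 of 27 lower and 0 higher (13 and 0 over the list alone; adjusted p = 0.00099, and adjusted p = 0.51 with an estimated correlation). Flavonoid genes were lower in 3 of 18 cases and higher in 0 (9 and 0 over the list alone; adjusted p = 0.0026, and adjusted p = 0.51 with an estimated correlation).

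Heat shock genes were lower at 12 d in 5 of 10 cases and higher in 0 (6 and 0 adjusted over the list alone; adjusted p = 0.0048, and adjusted p = 0.27 with an estimated correlation), but the calls of the 4 genes named here ended when single libraries were left out. HSP17.4 (AT3G46230) was at -2.98 (adjusted p = 0.018), and at 0.073 or 0.06 without control or infested replicate 4 (range over the alternatives 0.0037 to 0.073). HSFA2 (AT2G26150), the heat shock factor, was at -1.5 (adjusted p = 0.0089, and 0.1 without control replicate 2; range over the alternatives 0.0026 to 0.1). ATHSP22.0 (AT4G10250) had 0 counts in infested and 21 in control plants, at least 6.25-fold lower, and its call ended without control replicate 4 (adjusted p = 0.24; lowest over the alternatives 0.021) or any of the infested replicates. HSP17.6A (AT5G12030) was at -2.97 (adjusted p = 0.035), which held only where control replicate 3 was the library left out (range over the alternatives 0.017 to 0.12). Gibberellin and brassinosteroid metabolism had 4 of 15 genes lower and 1 higher (4 and 1 over the list alone; adjusted p = 0.027, and adjusted p = 0.077 with an estimated correlation). Glucosinolate breakdown had 3 of 9 higher and 1 lower (4 and 1 over the list alone; adjusted p = 0.0024, and adjusted p = 0.097 with an estimated correlation).

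**Figure D4:**
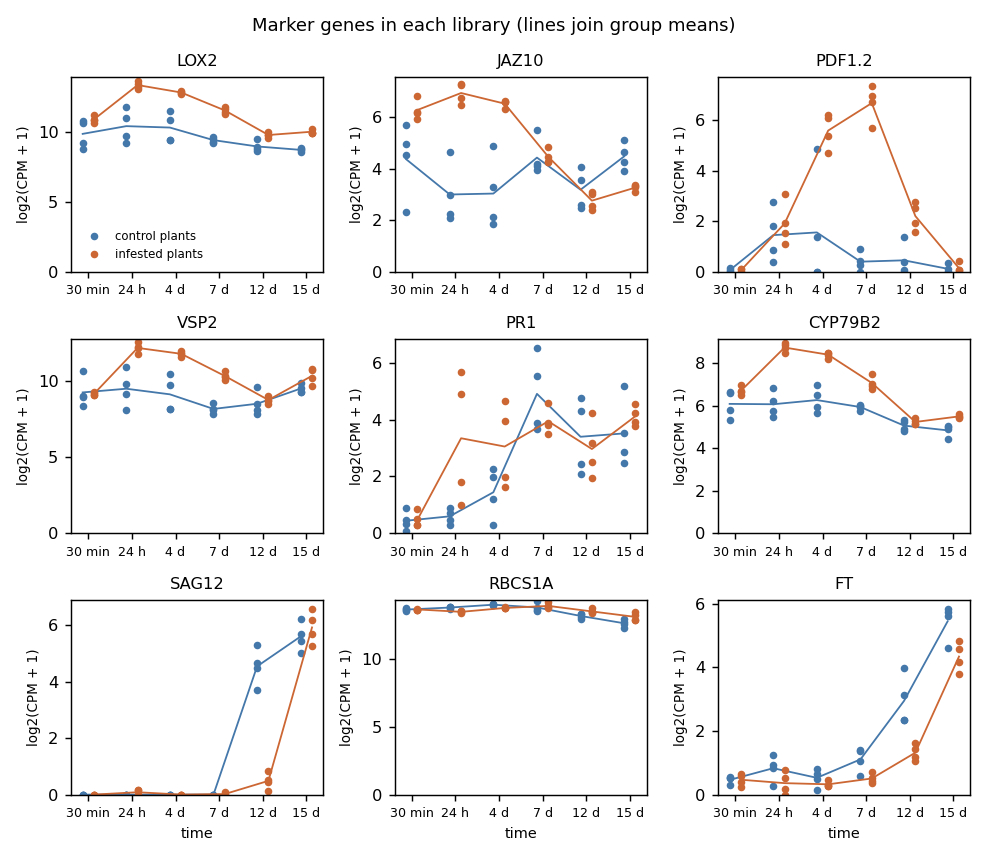
Level of 9 marker genes in each library (points, log2 of CPM + 1) at each time, with lines joining the group means of 4 libraries. SAG12 appeared in control plants at 12 d (24 CPM) before infested plants (0.424 CPM), and PDF1.2 peaked in infested plants at 7 d (109 CPM).

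At 15 d light harvesting (25 of 30 genes, adjusted p = 0.13 with an estimated correlation) and aliphatic glucosinolates (18 of 24, 0.077) were called higher and the rapid wound list lower (16 of 29, 0.069). Of the 87 chloroplast-encoded genes 22 were lower and 0 higher. ESM1 (AT3G14210), which steers glucosinolate breakdown towards isothiocyanates, went from 89.6 ± 22.3 to 346 ± 88.8 CPM (log2 fold change 1.95, SE 0.15, adjusted p = 1.4e-11). ATCSLA15 (AT4G13410), PLA2A (AT2G26560), a lipase gene, MSRB6 (AT4G04840) and FAR6 (AT3G56700) rose by 2.55, 2.18, 1.83 and 1.68, and CLH1 (AT1G19670), a chlorophyllase, LHB1B1 and the haemoglobin gene HB2 (AT3G10520) by 1.58, 1.57 and 1.40. TCH4 (AT5G57560), a touch-induced wall enzyme, was at 17 ± 1.64 CPM against 127 ± 25.6 (log2 fold change -2.90, SE 0.33, adjusted p = 1.8e-07). ERF6, PP2-B13, CYP707A3, the mitochondrial carrier gene DIC2 (AT4G24570) and WRKY53 were at -3.97, -3.62, -3.30, -3.27 and -3.10. FT was at 20 ± 6.51 CPM against 44.8 ± 14.7 (log2 fold change -1.16, adjusted p = 0.008, and 0.053 without infested replicate 2; range over the alternatives 0.0012 to 0.24). LOX2 was at 1.3 (adjusted p = 0.021), and at 0.067 and 0.057 without control replicate 2 and 4 (range over the alternatives 1e-04 to 0.2). No JA list was called at 12 d or 15 d (camera adjusted p at least 0.097). In total 1930 genes were higher and 2154 lower, 129 and 605 at least 2-fold. Library totals as the only scaling gave 1351 and 2823, and a fit of these 8 libraries alone 459 and 673. In that fit the calls of FAR6 (adjusted p = 0.12; lowest over the alternatives 3.2e-05) and HB2 (0.054; lowest 8.3e-09) ended. More genes were higher than lower with DESeq2 (2186 and 2106), no filter (2070 and 1678) and replicate number as a block (2198 and 1955). Control replicates 2 and 4 had 1.53% and 1.29% of their counts on chloroplast genes, against 0.0437% and 0.334% in the other controls and at most 0.473% in infested plants. Without both of them, 499 genes were higher and 594 lower and 17 of 38 named gene calls of this time ended, among them ATCSLA15, PLA2A and CLH1 (adjusted p = 0.15, 0.059 and 0.15; lowest over the alternatives 4.4e-06, 0.00012 and 1e-04). The number of genes higher in infested plants at 15 d was 1147 without control replicate 2, 1194 without control replicate 4 and 978 without infested replicate 2. The number of genes lower in infested plants at 15 d was 1308, 1297 and 1107 in these fits and 1366 without infested replicate 1.

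Aliphatic glucosinolate genes were higher at 15 d in 18 of 24 cases and lower in 0 (22 and 0 adjusted over the list alone; camera adjusted p = 5.8e-19, and adjusted p = 0.077 with an estimated correlation). SOT17 (AT1G18590), GSTU20 (AT1G78370), IMD1 (AT5G14200) and CYP79F1, all enzymes of the pathway, were at 0.96, 0.93, 0.90 and 0.78, and MYB28 at 0.47 (adjusted p = 0.00036). Without control replicates 2 and 4, those of high organellar share, IMD1 was at 0.47 (adjusted p = 0.081), CYP79F1 at 0.43 (0.18) and MYB28 at 0.28 (0.1). A fit of the 8 libraries of this time alone ended the calls of GSTU20 (0.071), IMD1 (0.11), CYP79F1 (0.071) and MYB28 (0.055), for which the lowest adjusted p over the alternatives was 5.5e-07, 1.1e-06, 2.3e-05 and 4.8e-06. Light harvesting had 25 of 30 genes higher and 0 lower (30 and 0 over the list alone; adjusted p = 6.7e-23, and adjusted p = 0.13 with an estimated correlation), with PSAN (AT5G64040), CAB1 (AT1G29930), LHCB6 (AT1G15820) and CAB3 (AT1G29910) at 0.72, 0.71, 0.70 and 0.70. Carbon fixation had all 10 genes higher (10 over the list alone; adjusted p = 4.4e-11, and adjusted p = 0.087 with an estimated correlation). The Rubisco small subunit genes RBCS1B (AT5G38430), RBCS2B (AT5G38420), RBCS3B (AT5G38410) and RBCS1A (AT1G67090) were at 0.78, 0.58, 0.48 and 0.47. Without infested replicate 2 the adjusted p was 0.087 for RBCS3B and 0.071 for RBCS1A, and it was 0.052 for RBCS3B without control replicate 4 (ranges over the alternatives 0.00095 to 0.32 and 0.00098 to 0.24). Without control replicates 2 and 4, PSAN was at 0.38 (adjusted p = 0.15), RBCS1B at 0.47 (0.14), RBCS2B at 0.35 (0.11), RBCS3B at 0.26 (0.32) and RBCS1A at 0.30 (0.24). These calls also ended in the fit of the 8 libraries alone (0.084, 0.097, 0.087, 0.15 and 0.12). The lowest adjusted p over the alternatives was 4.8e-05 for PSAN, 4.9e-05 for RBCS1B and 2.9e-05 for RBCS2B. Chlorophyll synthesis had 9 of 13 genes higher and 0 lower (12 and 0 over the list alone; adjusted p = 5.2e-10, and adjusted p = 0.069 with an estimated correlation).

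The cell wall loosening and cell division lists were also called higher at 15 d. Cell wall loosening had 7 of 13 genes higher and 0 lower (7 and 0 adjusted over the list alone; adjusted p = 1.7e-06, and adjusted p = 0.06 with an estimated correlation), with the expansins EXPA15 (AT2G03090), EXPA1 (AT1G69530), EXPA10 (AT1G26770) and EXPA6 (AT2G28950) at 0.91, 0.73, 0.67 and 0.59. Cell division had 8 of 21 higher and 0 lower (9 and 0 over the list alone; adjusted p = 7.9e-05, and adjusted p = 0.42 with an estimated correlation). The DNA synthesis genes TSO2 (AT3G27060), MCM2 (AT1G44900) and PCNA1 (AT1G07370) and the cyclin CYCA1;1 (AT1G44110) were at 0.57, 0.57, 0.49 and 0.58. The mitotic cyclin CYCB1;1 (AT4G37490) was at 0.22 (adjusted p = 0.44). Left-out libraries ended the calls of MCM2 (infested replicate 2, adjusted p = 0.055; range over the alternatives 4e-04 to 0.21) and CYCA1;1 (control replicate 2 or 4 or infested replicate 2, adjusted p = 0.063, 0.069 and 0.07; range over the alternatives 0.0021 to 0.47). Without control replicates 2 and 4, MCM2 was at 0.40 (adjusted p = 0.21), CYCA1;1 at 0.25 (0.47) and PCNA1 at 0.34 (0.18; lowest over the alternatives 4.3e-05). The fit of the 8 libraries alone ended the calls of MCM2 (0.071), CYCA1;1 (0.14), PCNA1 (0.12) and EXPA6 (0.064; lowest 5.8e-07). Glucosinolate breakdown had 4 of 9 higher and 1 lower (5 and 1 over the list alone; adjusted p = 0.00017, and adjusted p = 0.06 with an estimated correlation). Indole glucosinolates had 4 of 19 higher and 1 lower (6 and 2 over the list alone; adjusted p = 0.017, and adjusted p = 0.51 with an estimated correlation). The rapid response had 16 of 29 lower and 0 higher (17 and 0 over the list alone; adjusted p = 1.7e-14, and adjusted p = 0.069 with an estimated correlation). ABA synthesis and response had 6 of 23 lower and 0 higher (11 and 0 over the list alone; adjusted p = 6.4e-07, and adjusted p = 0.28 with an estimated correlation). Senescence had 6 of 13 lower and 0 higher (7 and 0 over the list alone; adjusted p = 0.00028, and adjusted p = 0.18 with an estimated correlation).

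The change of the infestation effect over time was tested directly. It differed among the 6 times for 9141 genes (41.1%). Between 30 min and 24 h it differed for 2447 genes, with NATA1, THI2.1 and EARLI1 gaining most (differences of 5.88, 5.52 and 5.22 on the log2 scale, adjusted p = 0.0067, 0.017 and 8.2e-06). Between 24 h and 4 d it differed for 748 genes, 617 of them with a lower effect at 4 d. The wound-response regulators ORA47 (AT1G74930) and STZ (AT1G27730, also ZAT10) and the carrier DIC2 led these at -6.08, -5.50 and -5.44. Between 4 d and 7 d it differed for 795 genes, with PDF1.3, PDF1.2b and AACT1 the largest gains, all with few or no counts in control plants at 7 d. From 7 d to 12 d it differed for 446 genes, among which DXPS1, the monoterpene synthase gene TPS10 (AT2G24210) and CYP82G1 lost most (-5.54, -5.48 and -5.15). Between 12 d and 15 d the effect differed for 157 genes, led by SAG12 at 6.17 (adjusted p = 2.8e-05), with CML37 at 2.53 and the growth gene EXO (AT4G08950) at -2.08. With DESeq2 the counts of these last intervals were 717 and 354, and in fits of the libraries of those times alone 336 and 35. With replicate number as a block the differences of PDF1.3, PDF1.2b, TPS10 and CML37 did not pass (adjusted p = 0.18, 0.094, 0.071 and 0.11; lowest over the alternatives 6.4e-19, 0.0065, 0.0011 and 0.0075). Across genes, log2 fold changes correlated by 0.52 between 24 h and 4 d, by -0.18 between 24 h and 12 d and by 0.47 between 12 d and 15 d, with the caveat that genes are not independent replicates. Of the genes called at both 24 h and 12 d, 949 moved in opposite directions, 129 were higher at both times (224 for independent lists) and 187 lower at both (189). No library was shared between times.

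Few genes moved the same way throughout. The number higher at all 6 times was 6, against 0.0138 for independent calls, and the number lower at all 6 was 9, against 0.0103. Library totals as the only scaling gave 3 and 21, and DESeq2 11 higher. They lie outside the rule for named genes and were picked after their values were seen. The higher genes were AT1G66920, AT3G16530, AT4G24350, the pectin methylesterase gene PME3 (AT3G14310, log2 fold changes from 0.54 to 1.04), the cyanide-detoxifying CYSC1 (AT3G61440, 0.17 to 0.57) and GPRI1 (AT2G20570, also GLK1, a regulator of chloroplast development, 0.34 to 0.72). The lower genes included the cytokinin response regulator ARR9 (AT3G57040, -0.34 to -0.79), the auxin response gene IAA1 (AT4G14560, -0.35 to -1.56) and CYP71A25 (AT3G48280), with AT1G33480, AT1G33700, AT1G62510, AT1G72200, AT2G29300 and AT4G29905. Over all times 12206 genes (54.9%) were called at 1 or more, and 2736 (12%) were higher at some time and lower at another.

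Control plants were compared between the first and the last harvest as a measure of age. From 30 min to 15 d, 8110 genes were higher and 6321 lower in control plants (4273 and 2022 at least 2-fold). The clock genes LHY, CCA1, PRR9 (AT2G46790) and PRR7 (AT5G02810) were at 3.26, 0.98, -2.09 and -1.35 in this comparison, so the hour of harvest was not separated from age. The floral identity gene AP1 (AT1G69120) went from 0.823 ± 0.369 to 18.4 ± 3.88 CPM and FT from 0.38 ± 0.108 to 44.8 ± 14.7 CPM in control plants. The 300 genes most raised and 300 most lowered with age were chosen on control libraries of this study, so they are no independent evidence of age itself. At 12 d, 103 of the raised genes were lower in infested plants and 2 higher (136 and 3 adjusted over the list alone; camera adjusted p = 8.2e-21, and 0.016 with an estimated correlation). Of the lowered genes, 156 were higher and 4 lower (187 and 6 over the list alone; adjusted p = 4.3e-40, and 0.0038 with an estimated correlation). At 7 d the lowered genes were higher in 88 cases and lower in 20 (114 and 26 over the list alone; adjusted p = 4.4e-11, and adjusted p = 0.16 with an estimated correlation). The raised genes were lower in 17 and higher in 9 (14 and 8 over the list alone; adjusted p = 0.023, and adjusted p = 0.69 with an estimated correlation). At 4 d the lowered genes were higher in 79 cases and lower in 26 (92 and 38 over the list alone; adjusted p = 7.2e-05, and adjusted p = 0.49 with an estimated correlation). The other tests of these lists, both at 24 h and the raised genes at 4 d, did not pass (adjusted p = 0.57, 0.084 and 0.83). A score per library, the mean log2 CPM of the raised minus that of the lowered genes, was -0.92 ± 0.18 in infested and 0.42 ± 0.44 in control plants at 12 d. Infested libraries lay below all control libraries at 24 h, 4 d, 7 d and 12 d (exact permutation, two-sided, p = 0.029 each, the smallest 4 against 4 can give, adjusted p = 0.029 over these 4 times).

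**Figure D5:**
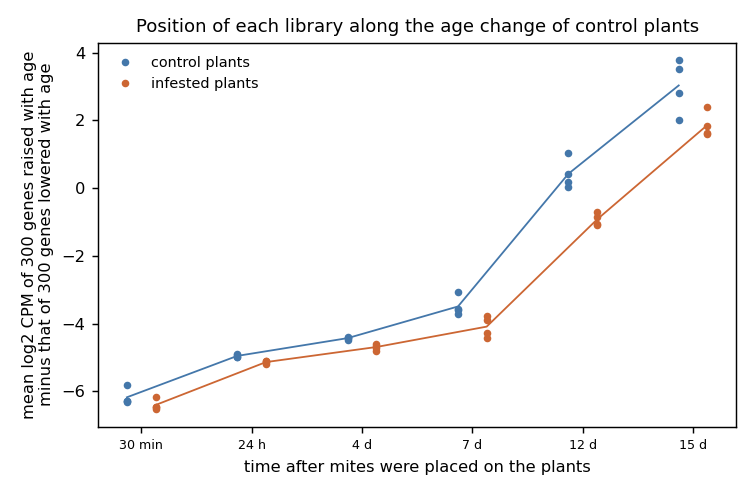
Score of each library along the age change of control plants (mean log2 CPM of 300 genes raised with age minus that of 300 genes lowered with age, vertical axis) at each time, with lines joining the group means. Infested libraries lie below the controls at 24 h, 4 d, 7 d and 12 d; the lists were made from the control libraries of 30 min and 15 d, so these times are no independent test.

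Markers of other organs and reference genes were not called as lists at any time. All 11 floral organ markers were measured in the aerial tissue, and their lowest adjusted p was 0.11, at 12 d, when 1 was lower and 0 higher (1 and 0 adjusted over the list alone). AP1 was at -0.39 (adjusted p = 0.21) at 12 d and 0.01 (adjusted p = 0.98) at 15 d. Of the 8 root markers 3 were measured, with the lowest adjusted p of 0.082 at 12 d (1 higher and 0 lower, and 2 and 0 over the list alone). Of the 6 seed markers only the albumin gene SESA1 (AT4G27140) was measured, at 3.01 ± 1.13 CPM in infested and 0.224 ± 0.228 CPM in control plants at 30 min. It also passed at 24 h (0.743 ± 0.321 against 0.0133 ± 0.0266 CPM) and at 4 d (0.217 ± 0.208 against 0 CPM), and the lowest adjusted p of the list test was 0.15. Between 1 and 3 of the 7 reference genes passed the gene-wise test at each time, with the lowest adjusted p of the list test 0.2 at 24 h. Median, mean and camera direction never differed in sign for a called list. They did so in 19 uncalled tests, among them ABA at 30 min (median -0.53, mean -0.42, direction up, adjusted p = 0.65), cytokinin at 24 h, JA biosynthesis at 7 d and 15 d, ethylene at 24 h, 7 d and 12 d, and the floral markers at 30 min, 24 h and 4 d. The rest were senescence at 30 min, gibberellin and brassinosteroid metabolism and cell division at 24 h, cell wall loosening, the clock and reference genes at 4 d, reference genes at 7 d, detoxification at 12 d and camalexin at 15 d.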

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

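All tests of explanations in this part were chosen after the result was seen, except the one on the scaling of the libraries. The infestation effect differed among the 6 times for 9141 genes, and between neighbouring times for 2447 (30 min and 24 h), 748 (24 h and 4 d), 795 (4 d and 7 d), 446 (7 d and 12 d) and 157 genes (12 d and 15 d). Each is a tested difference between times. Regrouping within the times also breaks up the infestation effect, so it cannot exclude chance for these 6 counts. In fits of the libraries concerned the real groups gave 2728, 1074, 811, 336 and 35 genes between neighbouring times and 9141 among all times. No other regrouping gave any (the real one was 1 of 40 for each interval and 1 of 22 for all times).

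The genes with the largest differences between neighbouring times were met in the report. From 30 min to 24 h these were NATA1 (5.88), THI2.1 (5.52) and EARLI1 (5.22), genes of JA-linked defence and cold or pathogen response. From 24 h to 4 d they were ORA47 (-6.08), STZ (-5.50) and DIC2 (-5.44), all quickly induced by wounding or stress. From 4 d to 7 d the defensins PDF1.3 (8.77) and PDF1.2b (7.65) and the acyltransferase AACT1 (7.28) led, fitted differences that rest on 0 to 2 counts in the control plants at 7 d and give no bound on size. From 7 d to 12 d the volatile terpenoid genes TPS10 (-5.48) and CYP82G1 (-5.15) and the isoprenoid gene DXPS1 (-5.54) lost most. From 12 d to 15 d the largest were SAG12 (6.17), CML37 (2.53) and EXO (-2.08).

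The rapid wound and pattern genes were lower in infested than in control plants from 4 d on. Different hours of harvest cannot be told apart from an effect of the mites. CCA1, LHY, PRR9 and PRR7 differed at 4 d by a median log2 of 0.22 (2 passing). In controls they moved by 1.02 from 30 min to 24 h and the list by -0.02. From 24 h to 4 d they moved by 0.36 (2 passing) and the list rose. A rise in the controls after 24 h goes with the pattern, with a median of 2.16 over the list at 4 d (21 of 29 higher and 0 lower), 1.99 at 7 d (22 and 1), 1.71 at 12 d (23 and 2) and 1.74 at 15 d (20 and 2). A fall in infested plants below the level of the 24 h controls is argued against at 4 d (median difference 0.56, 12 higher and 0 lower) and 7 d (0.61, 6 and 0). Both rest on camera with the preset correlation (p = 4.5e-05 and 0.00094), with no other list test run for them. Such a fall stays open at 12 d (0.41, 8 and 2) and 15 d (0.08, 7 and 7), where the list was not called against the 24 h controls. It stays open whether the control rise came from handling, from age or from another condition.

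Genes that change with plant age were less advanced in infested plants at 12 d. A single library is argued against, as the lowest control library and the highest infested library were 0.74 apart in the age score. A smaller share of flowers in the infested samples cannot be told apart from a delay. The floral organ markers had a median of -0.32, with an adjusted p of 0.11 by camera and 0.044 by fry. Slower development of infested plants may account for the pattern and stays a hypothesis. The lists also take in any effect of the hour of harvest between the controls of 30 min and 15 d, which was not separated from age.

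At 30 min 4.94 times as many genes rose as fell by at least 2-fold, while the infested libraries had lower totals. After thinning all 30 min libraries to equal totals the ratio was 5.06, which argues against depth. With library totals as the only scaling it was 4.02, which argues against the scaling. An early response to the mites or to their transfer may account for it, and these were not separated here.

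Some libraries stood apart from their group, a difference of a kind that chance gives in about 1 in 20 groups. Of 72 summary values 5 did so, and of 398 values of named genes 29 (7.29%). Infested replicate 2 at 30 min had 0.0816% of its counts on chloroplast genes (others 0.0301 to 0.0309) and 0.0159% on mitochondrial genes (others 0.00405 to 0.00488). Control replicate 4 at 12 d had 0.024% on chloroplast genes (others 0.0165 to 0.0175). Control replicate 1 at 15 d had 0.178% on features without a locus name (others 0.206 to 0.211). Control replicate 1 at 30 min had an age score of -5.80 (others -6.32 to -6.29).

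Other splits of the 8 libraries of each time tested whether chance can be excluded for the gene counts. It can at every time and in both directions, the real split being the only 1 of 35 with as many genes. The real split gave 3072 higher and 2199 lower genes at 30 min (highest other 0 and 1), 3146 and 2339 at 24 h (0 and 0), 2636 and 2746 at 4 d (0 and 0), 753 and 1202 at 7 d (1 and 0), 959 and 1080 at 12 d (32 and 1) and 459 and 673 at 15 d (3 and 0). For controls at 15 d against 30 min it gave 7232 and 5959 (0 and 0).

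For the number of called gene lists chance cannot be excluded at any time. The real split called 14 lists at 30 min (highest other 17; 5 of 35 splits with as many), 15 at 24 h (18; 6), 15 at 4 d (15; 2), 13 at 7 d (16; 7), 15 at 12 d (17; 5) and 13 at 15 d (18; 9). At 30 min, 24 h, 4 d and 12 d all other splits with as many lists exchange 1 library of each group, and so hold part of the real contrast. The splits with 2 of each group on either side called at most 10, 6, 9 and 11 lists at these times, but 14 at 7 d and 15 at 15 d. Chance stays open for the age lists. At 12 d the real split was first, the test's floor (1 of 35, camera p 5.7e-40, smallest other 1.4e-37, 8.6e-17 with 2 of each group). It was not at 24 h (15 of 35, 0.19 and 0.0028), 4 d (2 of 35, 0.00045 and 0.00039) or 7 d (5 of 35, 1.4e-09 and 2.8e-13).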

How the results depend on the processing

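The alternatives of 30 min libraries thinned to equal totals, organellar features left out, 15 d without the controls of high organellar share and age lists of 100 genes were chosen after the result was seen; the others were chosen before the data were examined. No named gene or called list changed direction under an alternative, but the side with more genes did. Library totals as the only scaling gave more lower than higher genes at 30 min, 24 h and 4 d, as did the 8 libraries alone at 4 d. More higher than lower genes came with no filter at 12 d and 15 d and with DESeq2 at 15 d. RLE normalization, no filter on low counts, leaving out organellar features and thinning kept every count of genes within 1.5 times. Among calls of named genes, RLE normalization and library totals as the only scaling kept 214 of 214, organellar features left out 199 of 199, DESeq2 208 of 212, no filter 210 of 214, thinning 24 of 26, the 8 libraries of a time 169 of 199 and leaving out each library in turn 1517 of 1592.

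Fits of only the 8 libraries of a time gave more lower genes at 4 d (2746) and fewer genes later: 753 higher at 7 d, 959 higher and 1080 lower at 12 d, and 459 and 673 at 15 d. Fits of the libraries of 12 d and 15 d alone gave 35 genes whose effect differed, against 157. Library totals as the only scaling gave 1003 higher and 2872 lower genes at 12 d, and 3 genes higher and 21 lower at all 6 times. DESeq2 gave 717 genes whose effect differed between 7 d and 12 d, 354 between 12 d and 15 d, and 11 genes higher at all 6 times. The cause was tested for none of these.

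Libraries were left out in turn for infested against control plants at each time, and not for the differences between times, the control plants with age or the gene lists. The counts were 814 to 1865 higher genes at 7 d, with the counts without control replicate 2 (814) and control replicate 3 (818) the ones moved by more than 1.5 times. At 12 d it gave 1097 (without control replicate 4) to 1654 higher genes. At 15 d it gave 978 to 2422 higher and 1107 to 2819 lower genes. The number of genes higher in infested plants at 15 d moved without infested replicate 2 (978), control replicate 2 (1147) and control replicate 4 (1194). The number of genes lower in infested plants at 15 d moved without these (1107, 1308 and 1297) and without infested replicate 1 (1366). Without both 15 d controls of high organellar share the counts were 499 and 594, and 17 of 38 named gene calls of that time ended. Each of these fits had fewer libraries; the cause was not tested.

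With an estimated correlation 7 of 75 list calls held and 2 of 5 age list calls. The lowered genes lost theirs at 4 d (adjusted p = 0.49) and 7 d (0.16), and the raised genes at 7 d (0.69). The raised genes at 7 d also lost it with fry (0.15), library totals as the only scaling (0.27) and lists of 100 genes (0.28); the cause was not tested. Fry ended the calls of cell division at 30 min (0.14) and 12 d (0.05), light harvesting at 24 h (0.061) and 7 d (0.08), ABA at 4 d (0.08) and indole glucosinolates at 15 d (0.058). It kept 69 of the 75 list calls, library totals as the only scaling 74 and RLE normalization 75.

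Replicate numbers were also tried as a block within each time. Of 24 pairs of equal number only 4 correlated above 0.1 (median 0.0155, -0.5 to 0.25), so the numbers were not read as a pairing. The block kept every count of genes within 1.5 times, 206 of 214 named gene calls and 73 of 75 list calls, ending cell division at 30 min (0.059) and heat shock at 7 d (0.062). With it more genes were higher than lower at 12 d (1955 and 1805) and 15 d (2198 and 1955). It ended the calls of a difference between times for PDF1.3 (adjusted p = 0.18), PDF1.2b (0.094), TPS10 (0.071) and CML37 (0.11). CML37 also lost it with no filter (0.051).

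Depth limited genes with few counts: 15 named results had 3 or fewer counts in 1 group and are given as bounds or with counting intervals.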

Other observations

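In infested plants at 15 d, 22 of 87 chloroplast-encoded genes were lower and 0 higher (median log2 fold change -1.16). Of 33 mitochondria-encoded genes 19 were lower and 0 higher (median -1.52). At the other times at most 2 genes of either class passed. Control replicates 2 and 4 had the highest chloroplast (1.53% and 1.29%) and mitochondrial shares (0.134% and 0.193%) at 15 d. Control replicate 3 (0.0437% and 0.00933%) lay below every infested library. The root-expressed myrosinase gene PYK10 (AT3G09260) was higher in infested plants at 24 h (log2 fold change 1.15), 4 d (0.72), 7 d (0.67) and 12 d (0.58).

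The homoterpene pathway moved as a pair of genes picked after their values were seen: TPS04, which makes the precursor, was at 2.53, 4.05, 4.58 and 3.58 at 30 min, 24 h, 4 d and 7 d, and CYP82G1 at 5.19, 5.03, 5.50 and 4.77. At 12 d and 15 d neither passed. Features without a locus name held 0.205 to 0.258% of the counts in control and 0.363 to 0.404% in infested libraries at 30 min.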
